A study of Chlamydomonas reinhardtii with 9 samples.

How the data were processed

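Chromatin immunoprecipitation with an anti-HA antibody followed by sequencing (ChIP-seq) was measured in Chlamydomonas reinhardtii. Per the labels, the series holds 3 libraries of a line named for PAF1, 3 of a line named for SKIP and 3 of the wild type, all in the CC5325 background. The labels give the genotypes of the first 2 groups as paf1 and skip, which does not settle whether the lines also carry a mutation. The design text describes these groups as HA-tagged lines, and they are called PAF1-HA and SKIP-HA here. Peak lists of the 3 PAF1-HA and 3 SKIP-HA libraries were used. Peaks of the wild-type libraries were not analysed here, so no background from untagged cells stands beside any value. The labels do not say whether replicates came from separate cultures. Each p-value that compares the groups therefore measures only the spread between these libraries, which may be technical. The p-values from shifted regions measure placement along the sequences and not the spread between libraries. Replicate 3 of each tagged group carries other label fields than replicates 1 and 2, and was treated as a possible batch.

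The deposited unit is a genomic interval, that is the start and end of 1 peak on 1 sequence, with 3 columns and no score, fold enrichment, p-value or strand. Each library has its own list, so the deposited peaks are given per library, not on pooled replicates. Between 99.96% and 99.98% of the intervals in each list were exactly 400 bp wide. Bowtie2 and HOMER are named for all 9 samples and MACS3 for 4 of them, without version, role or threshold, per the submitters' processing notes. The genome build, the calling threshold and the control library are not given in the sources used here. Peaks lay past the last gene of the version 5.5 gene table on 12 of 17 chromosomes. Sequence can continue past the last gene, so this alone does not show a different build. As the fit of that table to the peaks was not established, it was not used to place peaks in genes. Promoters, exons, introns, gene lists and base composition were therefore not analysed here. Coordinates below are 1-based positions in the files' own unnamed build. The read depth is unknown, since peak lists carry no counts of reads. A list's length moves with depth, enrichment and threshold together, and the absence of a peak is the absence of a call, not of protein.

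Before the data were examined, tests were fixed for peaks per library, similarity of libraries, consensus regions with their overlap, and gene-based results. The gene-based results and everything ranked by a peak score had no values to run on. In their place, regions with peaks in 3 libraries of one group and none of the other were counted by position, and 100 kb windows were tested. The window test, the shares per chromosome, the stitched domains, the organelle comparisons, the local shifts, the shifts of domains, the counts over mixed sets of 3 libraries and the random thinning of lists were chosen after the data had been examined. The rule for named genes allowed, without a fitting annotation, the 10 best-ranked regions of each kind. With no score to rank by, regions with exactly 1 peak in each library concerned were ranked by the distance between their outermost peak centres, a rule chosen after the data were seen. Chromosomes, windows and domains named in the text were also chosen after their values were seen.

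Overlaps were computed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9. The base-pair Jaccard index (shared over combined covered length) was computed for each pair of libraries. Peaks overlapping by at least 1 bp were merged within a group, and a merged region with a peak in at least 2 of 3 libraries was a consensus region. Overlap between the groups' consensus regions was compared with 1000 circular shifts of the regions along each sequence, one-sided. A second comparison moved the regions by 2 to 10 kb. Peaks of all 6 libraries were merged in the same way for counts of regions by library. Values per library were compared by two-sided exact permutation tests, which with 3 against 3 libraries cannot give a p below 0.1. Shares of peaks given for single libraries carry 95% Wilson intervals, which cover counting error only.

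Peaks per 100 kb window were tested with limma 3.58.1 in R 4.3.3. The values were log2 shares of the library's peaks with 0.5 added to each window, over windows with a mean of at least 5 peaks per library. Benjamini-Hochberg adjustment was applied over the 1068 windows that passed, with a threshold of 0.05. On simulated Poisson counts for these 1068 windows, with 200 windows changed, 78% of windows changed 2-fold and 92% of those changed 3-fold were recovered. These rates depend on that number of changed windows and that spread, and do not give the power on the real lists. In that simulation 1.15% of unchanged windows were called, and 0 windows were called when none had changed. On 2 simulated lists of randomly placed intervals, the overlap corrected for that of shifted intervals was 19.2% and 48.8% where 20% and 50% were shared. Overlaps of consensus regions are given below without that correction, beside the shifted percent. Alternatives tried were each library left out, replicates 1 and 2 only, a block on the replicate number, assembled chromosomes only, other consensus and overlap rules, uniform shuffling, thinning to 16329 peaks per list, and other window sizes and filters.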

Results

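PAF1 is the name-giving subunit of a complex that travels with RNA polymerase II during transcript elongation, and SKIP is an SNW-domain protein with roles in splicing and transcription. The series title names both in a single module with CDKB, a plant-type cyclin-dependent kinase of the cell cycle. Chromatin from the unicellular green alga Chlamydomonas reinhardtii was precipitated with an antibody against the HA epitope tag, in a PAF1-HA line and a SKIP-HA line. The data described here are 1 peak list for each of 3 PAF1-HA and 3 SKIP-HA libraries. Nearly all peaks were intervals of 400 bp without a score, and the read depth behind them is unknown.

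The first comparison asked how many positions each tagged protein yielded. SKIP-HA libraries held more peaks than PAF1-HA libraries, and the groups did not overlap. PAF1-HA libraries had 16329, 16998 and 17645 peaks, with a mean of 16991 ± 658 (SD, n = 3). SKIP-HA libraries had 19709, 22305 and 24680 peaks, with a mean of 22231 ± 2486 (SD, n = 3). The SKIP-HA mean was 1.31 times the PAF1-HA mean, with a two-sided exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. PAF1-HA peaks covered 6643 ± 252 kb, or 5.91% of the length spanned by peaks, and SKIP-HA peaks covered 8676 ± 951 kb, or 7.71% (SD, n = 3). Peaks of both proteins were clustered. In PAF1-HA libraries 50.1% ± 0.484 of peaks had a neighbour with its centre within 1 kb, and in SKIP-HA libraries 53.2% ± 2.35 did (SD, n = 3). Random placement of the same peaks gave 25.3% to 27.1% in PAF1-HA libraries and 29.7% to 35.8% in the longer SKIP-HA lists. Replicates 1 and 2, which share a set of label fields, differed between groups by 4344 peaks (SKIP-HA minus PAF1-HA) against 5241 over all libraries; replicate 3, with other fields, is 1 library per group.

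By the Jaccard index of the whole lists, libraries of the same protein resembled each other slightly more than libraries of different proteins. Relative to shifted peaks this held for PAF1-HA only, as it did after random thinning of every list to the same length. After thinning the mean index was 0.152 within SKIP-HA, 0.161 between groups and 0.210 within PAF1-HA. The lowest pair within SKIP-HA, at 0.140, then lay below the highest pair between groups, at 0.181. Thinning lowers the SKIP-HA value most by construction. It also lowers the value between groups and takes few peaks from the PAF1-HA lists. Whether SKIP-HA libraries resemble each other more than they resemble PAF1-HA libraries at equal depth is therefore not decided. On the whole lists, the mean Jaccard index was 0.219 ± 0.00262 among PAF1-HA libraries and 0.213 ± 0.00415 among SKIP-HA libraries (SD, n = 3 pairs each). Between a PAF1-HA and a SKIP-HA library it was 0.193 ± 0.00484 (SD, n = 9 pairs). The lowest pair within a group, at 0.211, lay above the highest pair between groups, at 0.201. The difference of 0.0233 between the within-group and between-group means was reached by 1 of the 10 splits of the 6 libraries, the real one (exact permutation p = 0.1, the smallest possible). The next highest split gave -0.000715. Within replicates 1 and 2 the difference was 0.0229. Relative to shifted peaks, pairs of PAF1-HA libraries shared 4.51-fold to 4.79-fold more peaks, pairs of SKIP-HA libraries 3.34-fold to 3.78-fold and pairs between groups 3.45-fold to 4.05-fold. Shifted peaks hit longer lists more often, so these folds are not independent of list length. Shifted peaks of PAF1-HA replicate 1 met PAF1-HA replicate 2 in 11.0%. Those of SKIP-HA replicate 2 met SKIP-HA replicate 3 in 15.9%. Where peaks of different libraries overlapped, the median distance between their centres was 78.8 ± 4.99 bp between groups (SD over 9 pairs) and 79.8 ± 3.87 bp within groups (SD over 6 pairs), a difference smaller than the spread over pairs.

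**Figure D1:**
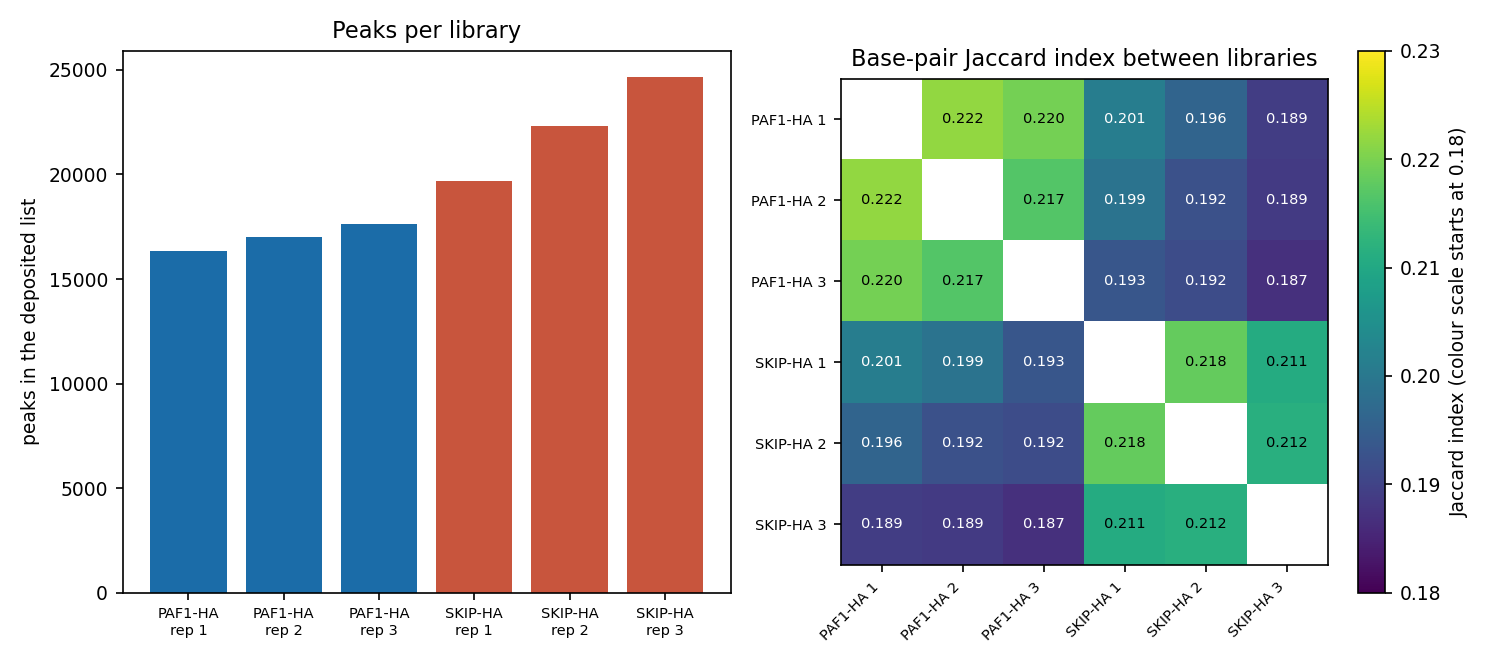
Left, number of peaks in each library's list (bars start at 0; blue PAF1-HA, red SKIP-HA), from 16329 to 24680. Right, base-pair Jaccard index of each pair of libraries, on a colour scale that starts at 0.18; pairs within a group lie at 0.211 or above and pairs between groups at 0.201 or below.

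The main comparison asked whether PAF1-HA and SKIP-HA peaks lay at shared positions. PAF1-HA had 13045 consensus regions, with a median width of 565 bp, and SKIP-HA had 16812, with a median width of 576 bp. Of the PAF1-HA regions, 8595 overlapped a SKIP-HA consensus region, which is 65.9%, against 17.9% ± 0.391 (SD over 1000 shifts) after circular shifts, a 3.67-fold excess. Of the SKIP-HA regions, 8701 overlapped a PAF1-HA consensus region, which is 51.8%, against 14.0% ± 0.300, a 3.70-fold excess. The permutation p from the shifts was 0.000999 for each group, the smallest that 1000 shifts can give. Shifts test placement only, here and below. A background common to both lines would also raise the overlap. The wild-type libraries, which bear on this, were not analysed here. Against shifts of only 2 to 10 kb, which keep the local density of peaks, the excess was 2.88-fold for PAF1-HA and 2.90-fold for SKIP-HA. Counting any SKIP-HA peak, 89.4% of PAF1-HA consensus regions were overlapped and 1384 were not. Counting any PAF1-HA peak, 77.0% of SKIP-HA consensus regions were overlapped and 3860 were not. Random thinning of every list to 16329 peaks, which takes more peaks from the longer SKIP-HA lists and so lowers their consensus number by construction, left 12507 PAF1-HA regions, of which 48.3% overlapped, and 11578 SKIP-HA regions, of which 52.0% overlapped, with the order of the groups turned round for both. The numbers of consensus regions fell to between 7687 and 7871 for PAF1-HA and between 9522 and 10509 for SKIP-HA when any 1 library of that group was left out, and the percentages fell to as low as 42.7% and 33.1% when 1 library of the other group was left out. With replicates 1 and 2 only, the percentages were 49.4% for PAF1-HA and 40.3% for SKIP-HA, with a 5.18-fold excess over shifted regions for each group.

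Merging the peaks of all 6 libraries gave 37052 regions. A peak in every library was found for 3047 of them, or 8.22%, while lists shifted independently gave a mean of 12.1 such regions and a maximum of 18 over 20 draws. A peak in only 1 library was found for 13107 regions, or 35.4%. Among the regions with exactly 1 peak in each of the 6 libraries, the peak centres agreed most closely on chromosome 17 at 344352 to 344753, where all lay within 2 bp. Further such regions lay on chromosome 7 at 4961966 to 4962369, with centres within 4 bp, and on chromosome 14 at 4200674 to 4201078, with centres within 5 bp. The latter ends at the last position covered by any peak on chromosome 14. Chromosome 1 at 5697488 to 5697893, chromosome 9 at 3921530 to 3921935, chromosome 13 at 3715732 to 3716137 and chromosome 14 at 4182506 to 4182911 had centres within 6 bp. Chromosome 3 at 9228779 to 9229185, chromosome 8 at 1019821 to 1020227 and chromosome 10 at 2269947 to 2270353 had centres within 7 bp.

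**Figure D2:**
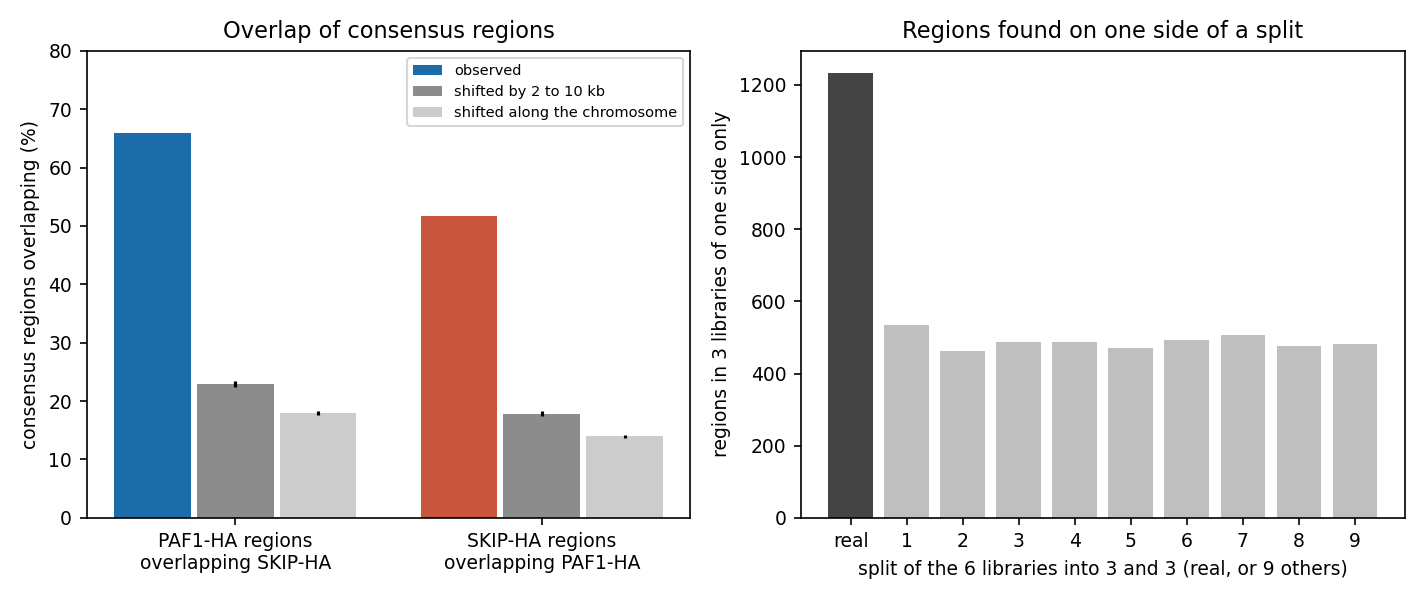
Left, percent of each group's consensus regions that overlap the other group's, observed (coloured) and after local or chromosome-wide shifts (grey; error bars are the SD over shifts); the observed bars stand at 65.9% and 51.8%. Right, number of regions with peaks in 3 libraries of one side and none of the other for the real grouping, 1233, and for the other 9 splits of the 6 libraries, at most 535.

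Of the 37052 regions, 18351, or 49.5%, had peaks of one protein only, 5290 of them of PAF1-HA and 13061 of SKIP-HA, most in a single library. Regions with a peak in every library of one protein and in none of the other numbered 1233, or 3.33%. A peak in 3 of 3 PAF1-HA and 0 of 3 SKIP-HA libraries was found for 310 regions, and the opposite for 923 regions. Lists shifted independently, which keep their lengths and lose the agreement between replicates, gave means of 130 and 328 such regions over 20 draws. Of the 18 sets of 3 libraries that mix the groups, 3 had at least as many regions of their own as PAF1-HA and 0 as many as SKIP-HA, with a range of 169 to 357 on the whole lists, which differ in length. With 1 library left out, the numbers rose to between 521 and 742 for PAF1-HA and between 1356 and 2224 for SKIP-HA, since fewer libraries were then required. Among PAF1-HA regions of this kind with 1 peak per library, the closest centres lay on chromosome 16 at 5921357 to 5921758, within 2 bp, on chromosome 16 at 7917464 to 7917866, within 3 bp, and on chromosome 3 at 6569666 to 6570069, within 4 bp. Next came chromosome 13 at 4030843 to 4031247 and chromosome 15 at 1363108 to 1363512, both within 5 bp, and chromosome 8 at 1017812 to 1018219, within 8 bp. The remaining 4 of the 10 named regions, with centres within 13 to 15 bp, started at 3125635 on chromosome 3, 757324 on chromosome 14, 2068543 on chromosome 16 and 3887692 on chromosome 4. Among SKIP-HA regions, the closest centres lay on chromosome 3 at 9252867 to 9253267, within 1 bp, on chromosome 5 at 1815325 to 1815727 and on chromosome 12 at 2015164 to 2015566, both within 3 bp. The chromosome 3 region ends at the last position covered by any peak on that chromosome. Whether this bears on the agreement of its centres was not tested. Centres within 5 bp were found on chromosome 2 at 1650321, chromosome 8 at 322952, chromosome 11 at 3192018, chromosome 12 at 4482439 and chromosome 16 at 7503381, and within 6 bp on chromosome 4 at 3847879 and chromosome 14 at 2526091, all given as start positions. The larger number for SKIP-HA could not be judged apart from the longer lists. After thinning every list to 16329 peaks, 542 ± 15 regions were PAF1-HA-only and 440 ± 17 were SKIP-HA-only (SD over 20 draws), against a mean of 333 for the highest mixed set of 3 libraries in each draw, so the ratio of SKIP-HA to PAF1-HA went from 2.98 to 0.813. Thinning takes peaks without regard to their strength and lowers the SKIP-HA number by construction, as a region with 1 peak per SKIP-HA library keeps all 3 in 40.1% of draws by chance. It also raises the PAF1-HA number by construction. Regions with peaks in 3 PAF1-HA and 1 or 2 SKIP-HA libraries, 778 and 1501 on the whole lists, can lose their SKIP-HA peaks. The excess of PAF1-HA over the mixed sets after thinning therefore cannot be told apart from the thinning.

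Peaks of both proteins were spread over all 17 chromosomes, with small differences in their shares. Chromosome 14 had the highest density, with 184 ± 5.68 PAF1-HA and 226 ± 24.4 SKIP-HA peaks per Mb, and chromosome 15 the lowest, with 103 ± 1.89 and 140 ± 14.1 peaks per Mb (SD, n = 3). Chromosome 14 held 4.57% ± 0.120 of PAF1-HA peaks and 4.30% ± 0.0310 of SKIP-HA peaks, a ratio of 0.940. Chromosome 13 held 4.63% ± 0.0681 of PAF1-HA peaks and 4.85% ± 0.0639 of SKIP-HA peaks, a ratio of 1.05. The shares of the groups did not overlap on 10 of 17 chromosomes, where chance gives 10% of chromosomes and the other splits of the libraries gave 0 to 3. SKIP-HA shares were higher on chromosomes 3, 5, 11, 13 and 16, and PAF1-HA shares on chromosomes 2, 7, 9, 14 and 17. Each of these had an exact permutation p of 0.1, the smallest possible, and a Benjamini-Hochberg adjusted value of 0.17 over the 17 chromosomes.

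**Figure D3:**
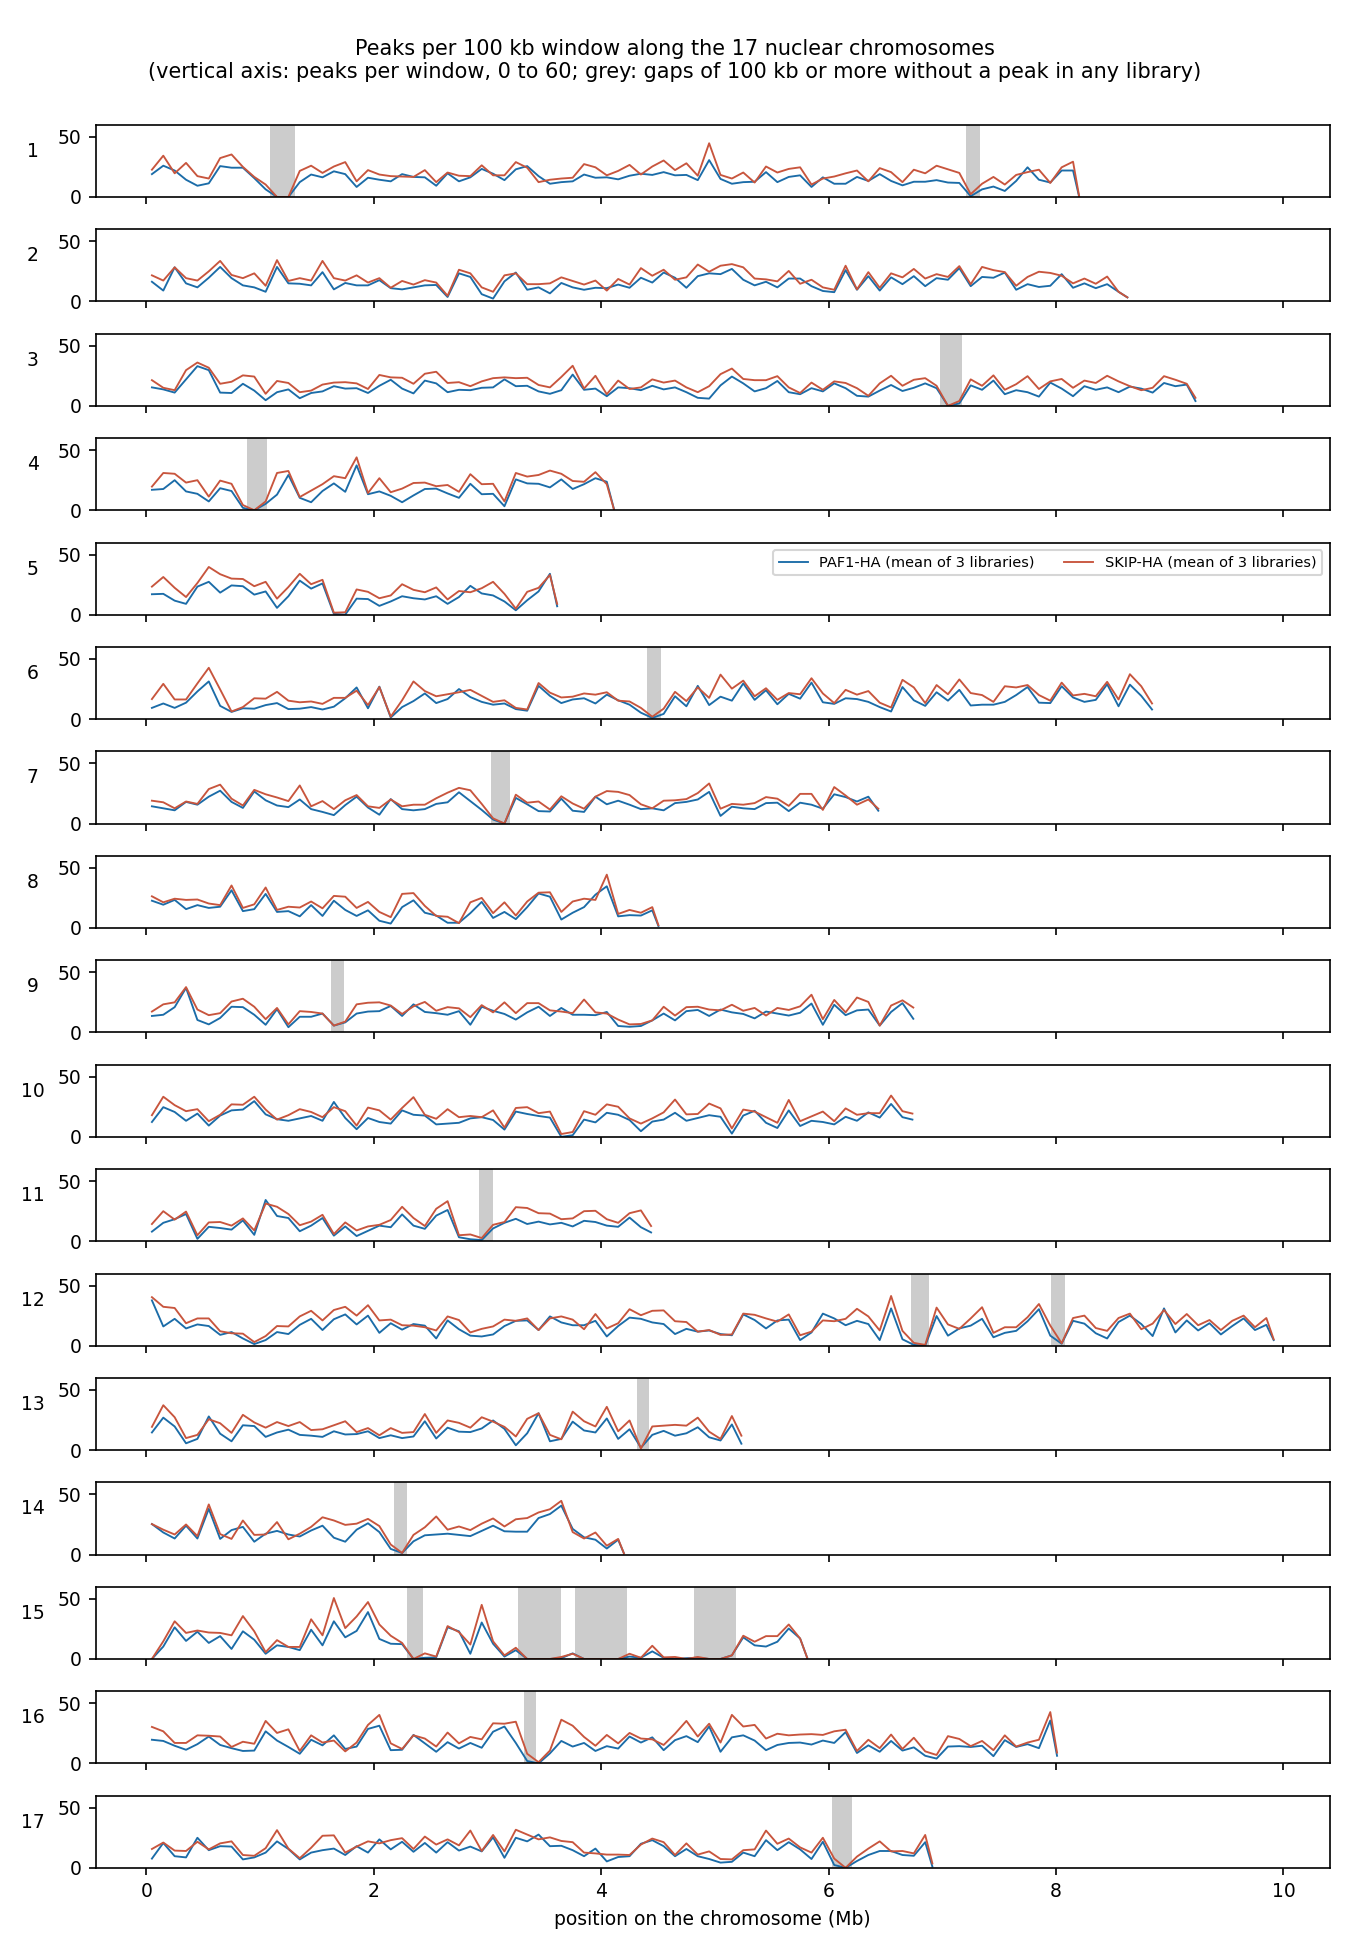
Mean number of peaks per 100 kb window (vertical axis) along each of the 17 chromosomes (horizontal axis, Mb) for PAF1-HA (blue) and SKIP-HA (red), each the mean of 3 libraries. The lines rise and fall together, and grey bands mark the 18 stretches of at least 100 kb without a peak in any library, 4 of them on chromosome 15.

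In 100 kb windows, 2 of 1068 tested windows differed between the proteins in their share of a library's peaks. These 2 calls come from a fit without a block on the replicate number. With that block, 13 windows were called higher in SKIP-HA and 14 in PAF1-HA. On chromosome 14 at 700001 to 800000, PAF1-HA libraries had 20.3 ± 2.08 peaks and SKIP-HA libraries 13 ± 4.58 (SD, n = 3), although the SKIP-HA lists were longer. The log2 ratio of SKIP-HA to PAF1-HA shares there was -1.06 (SE 0.225, limma adjusted p = 0.0140). On chromosome 4 at 1100001 to 1200000, PAF1-HA libraries had 13 ± 2.65 peaks and SKIP-HA libraries 31.0 ± 4.0, with a log2 ratio of 0.85 (SE 0.198, limma adjusted p = 0.0309). Beyond these, the windows with the lowest p in either direction had an adjusted p of 0.0544 and were not called. They included chromosome 16 at 3700001 to 3800000, with 14.0 ± 3.61 PAF1-HA and 31.3 ± 6.03 SKIP-HA peaks, and chromosome 12 at 5900001 to 6000000, with 26.7 ± 2.31 and 21.0 ± 1.00 peaks. Leaving out single libraries changed the calls more than the sizes. Over the 6 fits with 1 library left out, the log2 ratio ranged from -1.23 to -0.83 for the chromosome 14 window and from 0.74 to 0.98 for the chromosome 4 window. Both windows were called without PAF1-HA replicate 1 (limma adjusted p = 0.0214 and 0.0397) and without PAF1-HA replicate 3 (0.0128 for both, with 11 windows called higher in SKIP-HA and 7 in PAF1-HA). Neither was called without PAF1-HA replicate 2 (limma adjusted p = 0.0927 for both), without SKIP-HA replicate 1 (0.0703 for chromosome 14 and 0.0870 for chromosome 4) or without SKIP-HA replicate 2 (0.0881 and 0.0835). Without SKIP-HA replicate 3 only the chromosome 14 window was called (0.00498, against 0.0884 for chromosome 4).

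Neighbouring consensus regions formed longer domains for both proteins when regions at most 1 kb apart were stitched. PAF1-HA had 2371 domains of several regions, which held 47.0% of its consensus regions and had a median length of 1888 bp. SKIP-HA had 3298 such domains, with 51.2% of its regions and a median length of 1921 bp. Domains longer than 5 kb numbered 83 for PAF1-HA, of which 81 overlapped a SKIP-HA domain, and 129 for SKIP-HA, of which 123 overlapped a PAF1-HA domain. Circular shifts of these domains gave 47.9 ± 4.46 and 61.9 ± 5.65 overlapping ones (SD over 1000 shifts, permutation p = 0.000999 for each, the smallest possible). The median long domain was covered by domains of the other protein over 51.4% of its length for PAF1-HA and 39.4% for SKIP-HA. The longest domains of both proteins overlapped each other near the start of chromosome 3. The PAF1-HA domain spanned 72641 to 82434 (9794 bp) and the SKIP-HA domain 78581 to 93676 (15096 bp). Among the 10 longest SKIP-HA domains, the domain on chromosome 10 at 2023203 to 2032419 (9217 bp) overlapped 0 PAF1-HA domains, the domain on chromosome 9 at 6202406 to 6211903 (9498 bp) was covered to 4.35%, and the domain on chromosome 2 at 788155 to 798947 (10793 bp) was covered to 83.1% by PAF1-HA domains. Domain numbers and lengths were not compared between groups by a test.

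**Figure D4:**
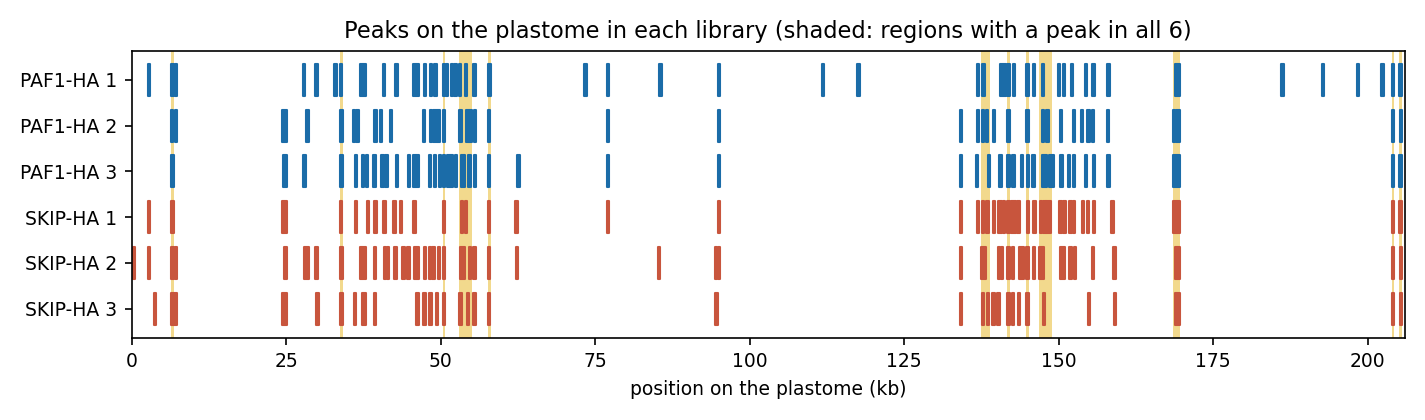
Position of each peak (horizontal axis, kb) on the plastome in the 3 PAF1-HA (blue) and 3 SKIP-HA (red) libraries, 1 row per library. Shaded bands are the 12 regions with a peak in all 6 libraries; libraries had 37 to 57 peaks each.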

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

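Of the tests in this part, only the comparison of list lengths by random thinning had its prediction written before its result was seen; the tests on organelles and the counts over splits were chosen after the results were seen.

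Peaks on the organelle genomes lie outside the nuclear comparisons and drew attention for that reason. The 6 lists held 297 peaks on the plastome and 31 on the mitogenome. Plastome peaks made up between 0.15% (95% Wilson interval 0.109 to 0.207) and 0.325% (0.248 to 0.424) of a library's peaks, with 0.300% ± 0.0315 in PAF1-HA and 0.220% ± 0.0605 in SKIP-HA libraries (SD, n = 3, exact permutation p = 0.1, the smallest possible, without overlap of the groups). They covered 9.70% ± 1.04 of the plastome in PAF1-HA and 9.17% ± 1.89 in SKIP-HA libraries (SD, n = 3, exact permutation p = 0.7), against 5.91% ± 0.225 and 7.72% ± 0.852 of the nuclear chromosomes, and 5 of 6 libraries lay above their own nuclear value. On the mitogenome they covered 13.1% ± 2.64 and 13.9% ± 1.58. Plastome regions with a peak in all 6 libraries numbered 12 of 64, the longest at 52914 to 54967 and 146856 to 148840, and 1 region was found in 3 libraries of PAF1-HA only and 1 in SKIP-HA only.

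Random scatter of false calls is argued against as the source of the plastome peaks, since the mean Jaccard index between libraries of different groups was 0.352 there, against 0.0495 and at most 0.0784 after shifts. A background common to both groups is a candidate explanation: the mean index within groups minus that between groups was -0.0109 on the plastome, and only 0.535% of 187 nuclear stretches of the same length lay at or below that value (median 0.0240). Both proteins sharing true positions on the plastome would give the same value. The wild-type libraries, which bear on this, were not analysed here, and no biological explanation was tested.

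The larger number of SKIP-HA-only than PAF1-HA-only regions, 923 against 310, may follow from the longer SKIP-HA lists, and the ratio fell from 2.98 to 0.813 (0.734 to 0.892 over 20 draws) when every list was thinned to the same length. This does not decide the question: random thinning alone keeps 40.1% of SKIP-HA regions with 1 peak per library, which by construction takes the ratio to 1.19 before any rise of the PAF1-HA number, and the bound set in advance against the explanation was out of reach. Longer lists and wider occupancy by SKIP therefore cannot be told apart, since depth, enrichment and peak strength were not measured. For the total of such regions, 1 of the 10 splits of the 6 libraries, the real one, gave as many as 1233, and the highest other split gave 535; with 10 splits a share under 0.05 cannot be reached.

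For the 100 kb windows, 1 of the 10 splits, again the real one, gave as many as 2 limma calls, and the highest other split gave 0, with 152 windows at an unadjusted p under 0.05 in the real split and 32 to 52 in the others. Here too the 10 splits are too few for a share under 0.05.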

How the results depend on the processing

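Added after the data were seen were random thinning, local shifts, replicates 1 and 2 only (except for similarity, where it was planned), assembled chromosomes only (except for peak numbers, where it was planned) and the window test with its settings. The higher peak number of SKIP-HA kept its direction under all 9 alternatives run (difference 4016 to 6502 with 1 library left out). The similarity within groups, pooled over both, minus that between groups also kept its direction under all 11 (0.0212 to 0.0266 with 1 left out). After thinning the pooled difference was 0.0195. The mean index within SKIP-HA, at 0.152, then lay below that between groups, at 0.161, while that within PAF1-HA was 0.210. Thinning lowers the SKIP-HA value most by construction, lowers the value between groups too, and takes few peaks from the PAF1-HA lists. The overlap of consensus regions stayed above shifted regions under all 14 alternatives run for each group (42.7% to 71.0% of PAF1-HA and 33.1% to 58.1% of SKIP-HA regions with 1 library left out). Numbers of regions moved by construction with the libraries required: consensus regions were 5266 and 6713 (PAF1-HA, SKIP-HA) when 3 of 3 libraries were needed, 26942 and 35044 when any 1 was enough, 7687 and 9522 with replicates 1 and 2 only, and 7687 to 13045 and 9522 to 16812 with 1 library left out. Regions of one group only were 1299 and 2562 with replicates 1 and 2 only, and 521 to 742 and 1356 to 2224 with 1 library left out. After thinning they were 542 and 440. Thinning lowers SKIP-HA numbers and raises the number of PAF1-HA-only regions by construction. It also turned round the order of the consensus numbers (12507 and 11578). Windows with a larger SKIP-HA or PAF1-HA share (1 and 1) numbered 1 and 2 at 50 kb, 4 and 2 at 200 kb, 3 and 1 without the filter on low windows, 1 and 3 with replicates 1 and 2 only, and 0 to 11 and 0 to 7 with 1 library left out; the cause was not tested. In window shares, replicate numbers did not visibly pair the libraries: correlations of deviations between same-numbered libraries were -0.00353, -0.0322 and 0.00226. Shares leave out list length, and the number of peaks rose from replicate 1 to 3 in both groups. Pairing in list length is therefore not excluded. With a replicate block, windows numbered 13 and 14, the difference in peak number was 5241 (exact sign-flip p = 0.25, the smallest possible), and the similarity difference of 0.0233 was reached by 1 of 4 swaps within numbers (exact p = 0.25). Not run, for lack of peak scores or of a gene annotation in the files' build, were the stricter threshold, equal list lengths by score, and every alternative for gene overlap, gene lists, peak position in genes and base composition. Unknown read depth limits every comparison of list lengths.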

Other observations

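The counts and tests in this part were all chosen after the data were seen.

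Some long stretches held no peak of either protein. There were 18 stretches of at least 100 kb without a peak in any of the 6 libraries, 3406 kb in all. Chromosome 15 held 4 of them, at 3768914 to 4230264 (461 kb), 3265709 to 3650088 (384 kb), 4816773 to 5186836 (370 kb) and 2291599 to 2435272 (144 kb), together 1359 kb. Outside these stretches chromosome 15 had 159 peaks per Mb and library, against 180 over all chromosomes outside theirs. The next longest lay on chromosome 1 at 1085071 to 1305744 (221 kb), chromosome 3 at 6979068 to 7171467 (192 kb) and chromosome 4 at 884340 to 1065926 (182 kb). Without a genome in the files' build, runs of unknown bases and repeats that reads cannot be placed in were not examined.

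Ranked by the sum of peaks over all 6 libraries, the first 3 of the densest 100 kb windows lay on chromosomes 15 and 14. The window on chromosome 15 at 1900001 to 2000000 had 39.0 ± 2.00 PAF1-HA and 47.3 ± 4.93 SKIP-HA peaks per library, and that on chromosome 14 at 3600001 to 3700000 had 40.7 ± 4.62 and 44.7 ± 1.15 (SD, n = 3), against a median window of 17.5 peaks per library. Among the 10 densest, the SKIP-HA mean was highest on chromosome 15 at 1600001 to 1700000, with 50.7 ± 5.51 peaks against 31.3 ± 3.51 for PAF1-HA. Across windows, Spearman's correlation of peak numbers averaged 0.794 within and 0.745 between groups; windows are not independent replicates. In the first 20 kb of the chromosomes, 12 of 35 regions, or 34.3%, had a peak in all 6 libraries, against 8.19% of regions over the nuclear chromosomes, although regions were sparse there, at 103 per Mb against 330 per Mb.

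Peaks found in a single library were more frequent in the longer lists, which are those of SKIP-HA. In PAF1-HA libraries 8.17% ± 1.12 of peaks overlapped no peak of another library, and in SKIP-HA libraries 14.4% ± 3.26 did (SD, n = 3, exact permutation p = 0.1, the smallest possible). Over the 6 libraries the percent was higher in each longer list, from 7.40% in the shortest to 17.7% in the longest. After random thinning of every list to 16329 peaks, it was 11.7% ± 1.20 in PAF1-HA and 18.3% ± 2.75 in SKIP-HA libraries (SD, n = 3, exact permutation p = 0.1). Such thinning takes most peaks from the SKIP-HA lists and so leaves their peaks fewer partners by construction. Without peak scores no equal-length comparison free of this was made. The percent of peaks found again in another library of the same group was 70.7% ± 2.03 and 70.8% ± 4.66 (exact permutation p = 0.9).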
